A study of Oryza sativa with 6 samples.

How the data were processed

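RNA from the roots of 3 control and 3 treated rice samples was extracted with RNeasy kits, and 500 ng of total RNA per sample was labelled with Cy3 by the Quick-Amp method, per the labels' protocols. The samples were hybridised to an Agilent custom rice array. Per the file headers, the scans were read with Agilent Feature Extraction 11.5.1.1, and the array's design grid names the genome build IRGSP5. The submitters' processing notes name Agilent Feature Extraction too. The files give no chromosome positions, so none are printed.

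The deposited value table holds log2 values for 42249 probes on 6 arrays. Which software the authors used for it is not stated. Its 4 columns with scanner output were checked against that output: 97.9% to 98.5% of probes lay within 0.001 of log2 processed signal minus a constant near the array's 75th percentile. Each column matched its own array (r over 0.9999 in all 4, across probes) better than any other (r up to 0.98). How the authors combined the 1554 probes spotted more than once was not identified. The deposited scanner output gives processed intensity per spot, which per the file headers was background-subtracted and detrended within each array with no scaling between arrays, and also mean and background intensity. The median background was 19.5 to 26 intensity units. The number of arrays limits the precision, and dim signal limits genes near background.

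Control spots, 1417 per array, were left out. A probe was kept if it was well above background on both scanner arrays of at least 1 group and not marked as an outlier on any; 169 probes were marked. Probes of a gene were averaged on the log2 scale, which left 28743 probes and 25031 genes, 21933 of them with 1 probe. Gene names come from the scanner output's descriptions, which hold no blanks; the reference gene table matched 1 gene ID and was not used. Where a gene was not well above background on either scanner array of a group, its fold is a bound against a limit. The limit is the lowest signal of a probe well above background on those arrays. Some genes not well above background read above it, so the limit is a low one and a higher limit would give smaller folds. For 4 named genes a log2 difference is given in its place, because that bound exceeded the 6-array difference or equalled the fold of the scanner arrays.

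Groups were compared with limma 3.58.1 in R 4.3.3, treated minus control, with a linear model per gene, empirical Bayes moderation, 2-sided p and Benjamini-Hochberg adjustment at 0.05. The main comparison used the value table on 6 arrays, and the second the 4 arrays with scanner output, as log2 processed signal minus the 75th percentile. The 32 gene lists were defined by words in gene descriptions; because the descriptions hold no blanks, the word patterns were rewritten without blanks and otherwise kept. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, 31 in all, with Benjamini-Hochberg adjustment over them; fry and an estimated correlation were alternatives. The 4 narrowed lists, which leave out families that the patterns took in, were chosen after the files were read and before any change between groups was computed. Their adjusted p is over all 35 lists.

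The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule, since fewer than 10 genes passed, the text names every gene past the threshold, the 10 genes of each direction with the smallest p among described genes whose groups do not overlap, and for each list its members past the threshold, up to 4, or else the member with the smallest p. The other members named in the shifted lists were chosen after their values were seen, as were the families in the closing section. Alternatives were quantile normalisation, centring on the median, no filter on dim probes, a stricter filter, a variance trend with robust moderation, array weights, a replicate block, single probes, a fold minimum, each array left out in turn, and for the 4 scanner arrays normexp background correction with an offset of 50 and slide as a block. Added after seeing the data were a lowess correction (span 0.3) of each array for mean signal and then probe GC content, the same without treated replicate 1, specific probes only, and the failed patch left out. The patch was set as the range of rows and columns of the slide-block genes' spots with at least 3 others within a distance of 10.

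The fits were tested on simulated data for 25031 genes with changed genes added. With 6 arrays, 1.2%, 48.8%, 74.4% and 84% of genes changed by 1, 2, 3 and 4 log2 units were recovered, with 50 changed genes of each size and 4.4 false calls per draw on average; with 4 arrays 0% were recovered at every size. A list shifted by −0.5 was called in 20 of 20 draws and 1 of 600 tests of other lists was called. The simulated genes varied independently of each other. In the data the estimated correlations of the lower lists ran from 0.0265 to 0.326, so these list rates do not carry over to the data. Matched random lists, 10000 per list, were drawn within 10 classes of signal level and 5 of GC content. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.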

Results

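Transcript levels were measured in rice (Oryza sativa) roots 48 h after the start of treatment. Seedlings germinated in MS medium were moved to Hoagland's solution, a plant nutrient solution, and treated with Bacillus subtilis RR4, a soil bacterium that the series describes as promoting plant growth. The labels do not say what the control plantlets received. There were 3 control and 3 treated root samples, each hybridised to its own single-colour Cy3 array of 60-base probes. The labels call the samples biological replicates and do not say what separates them. The deposited value table held 42249 probes on all 6 arrays as log2 signal relative to each array's 75th percentile, so that 0 marks that percentile. The column medians were −3.10, −3.19 and −3.12 in the controls and −3.28, −3.05 and −3.03 in the treated samples. Scanner output was given for control replicates 1 and 2 and treated replicates 1 and 3, on which 66.3% to 71.1% of the spots lay well above background. Correlations between arrays, across genes, ran from 0.945 to 0.969 within groups and from 0.930 to 0.959 between groups. The number of arrays limits the precision. The median standard error of a log2 change was 0.305.

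The first comparison asked which root transcripts differed after exposure to the bacterium. In treated roots 6 of 25031 genes passed an adjusted p of 0.05, 2 higher and 4 lower. A similar to xyloglucan endotransglycosylase XET2 gene, Os11g0539200, of a family that cuts and rejoins xyloglucan chains in the primary cell wall, fell by 3.62 on the log2 scale (SE 0.22), from −2.22 ± 0.24 to −5.84 ± 0.07 (SD, n = 3). A haem peroxidase gene, Os10g0566800, went from −4.25 ± 0.11 to −7.39 ± 0.34 and was at least 6.75-fold lower. A MADS-box transcription factor gene, Os11g0658700, rose by 3.01 on the log2 scale (SE 0.23), from −6.32 ± 0.16 to −3.31 ± 0.22. A gene with a pectinesterase inhibitor domain, Os03g0829600, of a family that includes inhibitors of pectin-demethylating enzymes, went from −8.37 ± 0.17 to −5.06 ± 0.33 and was at least 4.46-fold higher.

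The remaining 2 genes that fell were Os04g0532400, described as similar to OSIGBa0125M19.13 protein, and Os01g0909150, a conserved hypothetical protein gene. Os04g0532400 went from −4.20 ± 0.41 to −7.66 ± 0.04 and was at least 8.66-fold lower. Os01g0909150 fell by 2.93 on the log2 scale (SE 0.23), from −3.39 ± 0.27 to −6.32 ± 0.12. Os10g0566800, Os03g0829600, Os04g0532400 and Os01g0909150 were not well above background on either scanner array of 1 group, and the bounds were computed on the scanner arrays. Here and below, a fold given as at least a value holds only against the lowest signal of a probe well above background. Some genes not well above background read above that signal, so these folds are not strict lower bounds. Os11g0539200 was above background on 1 of the 2 treated scanner arrays, and Os11g0658700 on 1 of the 2 control scanner arrays. The probe of Os11g0539200 was designed as cross-hybridising, so its signal may include other transcripts. The same limit holds for at least 1 probe of these genes named further on: Os01g0637500, Os01g0850700, Os02g0593500, Os02g0776900, Os04g0509600, Os07g0252400, Os08g0473900, Os08g0499300, Os09g0346500 and Os10g0503200.

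All 6 genes had an adjusted p of 0.0183 in limma's moderated test with Benjamini-Hochberg adjustment, and each of them separated all 3 treated from all 3 control arrays. The groups did not overlap in 23.8% of genes, 3105 higher and 2850 lower, where chance gives 10%. At an unadjusted p under 0.05 there were 4502 genes, where 1252 are expected by chance, and 679 genes had an adjusted p under 0.10. The count of 6 rests on single arrays: it was 725 without treated replicate 1, 545 higher and 180 lower, and 0 without any other array. The split also moved with the scaling, from 2 higher and 4 lower to 19 and 100 after quantile normalisation and to 2 and 19 with each array centred on its median; both counts held all 6 genes.

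**Figure D1:**
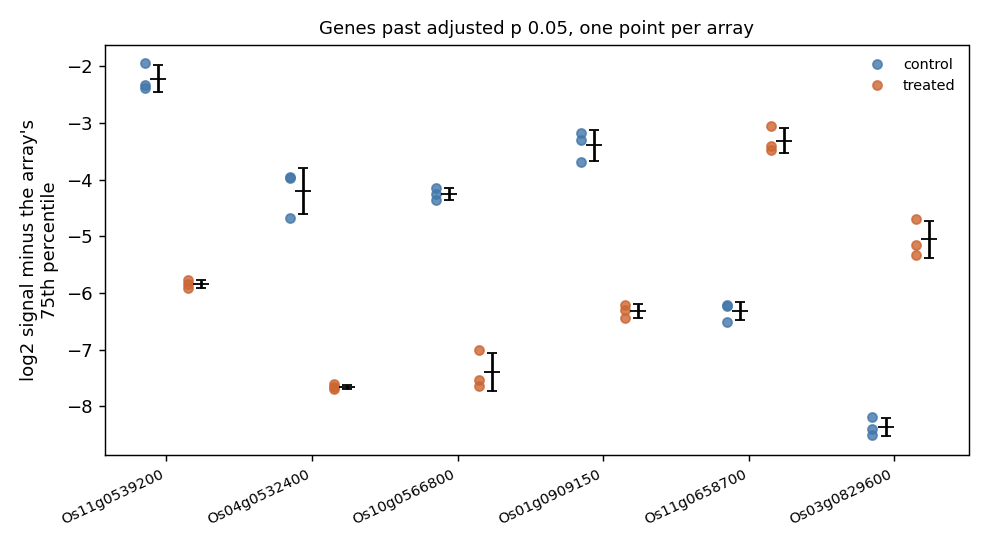
Log2 signal relative to each array's 75th percentile for the 6 genes past the threshold, with a point per array, 3 control and 3 treated, and the mean with its SD beside them. The control and treated points of each gene lie apart, for example −2.22 ± 0.24 against −5.84 ± 0.07 for Os11g0539200.

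Genes next in order of p, which separated the groups but did not pass, are given as values. The similar to lysine decarboxylase-like gene Os03g0109300 had a log2 difference of 2.51 (SE 0.29, limma adjusted p = 0.054). That of the alpha-amylase isozyme 3D gene Os08g0473900, a starch-degrading enzyme, was 3.87 (SE 0.56, limma adjusted p = 0.0628). The value for the glucoamylase-domain gene Os12g0504900 was at least 6.93-fold higher, with controls below background. The AAA-type ATPase gene Os07g0192700, also below background in the controls, differed by 2.83 (SE 0.35). The differences were 2.18 for the RCC1-domain gene Os03g0599600, 1.78 for the cystinosin/ERS1p repeat gene Os01g0266800, 2.32 for the F-box and cyclin-like domain gene Os08g0293200 and 1.72 for the similar to pollen-specific kinase partner gene Os01g0760300.

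Among lower genes outside the 6, the smallest adjusted p was 0.0512 in limma. The differences were −2.55 (SE 0.26) for the helix-loop-helix gene Os01g0630300, −2.48 (SE 0.26) for the desaturase/cytochrome b5 gene Os09g0338500 and −2.19 (SE 0.24) for the B-box zinc finger gene Os08g0249000. They were −2.67 (SE 0.29) for the pollen Ole e 1 allergen and extensin domain gene Os01g0726100 and −2.11 (SE 0.23) for the methyladenine glycosylase gene Os01g0799500. The SAM-dependent carboxyl methyltransferase gene Os11g0257700 was at least 4.33-fold lower and the copper-binding family gene Os01g0758000 differed by −2.69 (SE 0.30), both with treated signal below background. The spot of Os01g0758000 lies in a patch of the treated replicate 1 array where many spots read low.

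Of the 31 fixed gene lists with enough measured genes to test, 4 were called as shifted at the preset correlation, all downward. Directional fry called 0. Of the 10 splits of the 6 arrays into 3 and 3, 8 called at least 4 lists, the real split included. The count of lists thus does not set the real grouping apart. The list of cell wall loosening and synthesis had the smallest p, and its 168 measured genes had a median log2 difference of −0.48 (limma camera adjusted p = 7.19e-09; adjusted p = 0.977 with an estimated correlation). Over all genes 1 member rose, Os03g0829600, and 1 fell, Os11g0539200. Adjusted over the list alone, 2 rose and 44 fell, among them the similar to cellulose synthase BoCesA7 gene Os07g0252400 (−1.75, SE 0.22) and the similar to polygalacturonase gene Os01g0637500 (−2.70, SE 0.32; its probe also matches another locus), which act in cellulose synthesis and pectin cleavage. List means per array, relative to each gene's control mean, were −0.17, −0.04 and 0.21 in control replicates 1 to 3 and −0.67, −0.29 and −0.78 in treated replicates 1 to 3. With no filter on dim probes the list's median was −0.10 (limma camera adjusted p = 4.82e-06).

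The 100 class III peroxidases, secreted enzymes that oxidise phenolics and cross-link wall polymers, had a median of −0.39 (limma camera adjusted p = 0.000136; adjusted p = 0.985 with an estimated correlation). Of these, Os10g0566800 fell over all genes. Adjusted over the list alone 1 rose and 18 fell, such as the similar to class III peroxidase GvPx2b gene Os06g0546500 (−1.65, SE 0.24) and the peroxidase precursor gene Os04g0656800 (−2.11, SE 0.34). Treated means were −0.53, −0.24 and −1.01 against control means of 0.01, −0.32 and 0.31, so treated replicate 2 lay above control replicate 2. The median moved with single arrays, to −0.20 without control replicate 1, −0.59 without control replicate 2, −0.65 without treated replicate 1 and −0.14 without treated replicate 3. With no filter on dim probes it was −0.17. Over these and the other alternatives of the list test, apart from the estimated correlation, limma camera adjusted p ran from 1.2e-06 to 0.0227. With slide as a block on the 4 scanner arrays, where 1 treated array informs the difference, the median was −0.01.

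The 333 ribosomal protein genes had a median of −0.23 (limma camera adjusted p = 4.77e-06; adjusted p = 0.985 with an estimated correlation). No member passed over all genes; adjusted over the list alone 0 rose and 4 fell, among them the 40S ribosomal protein S7 gene Os03g0297100 (−1.67, SE 0.24) and the ribosomal protein S15 gene Os06g0177250, at least 2.26-fold lower. Treated means were −0.36, −0.03 and −0.30 against control means of −0.20, 0.09 and 0.11, so treated replicate 2 again lay above a control. With each array left out in turn the median ran from −0.36, without control replicate 1, to −0.18, without treated replicate 3.

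The 37 genes of nitrogen uptake and assimilation had a median of −0.38 (limma camera adjusted p = 0.0171; adjusted p = 0.977 with an estimated correlation). None passed over all genes or adjusted over the list alone. Treated means were −0.31, −0.15 and −0.50 against control means of 0.04, −0.21 and 0.17, so treated replicate 2 lay above control replicate 2. The ammonium transporter 1;1 gene Os04g0509600, a root uptake transporter family, differed by −1.21 (SE 0.32, limma adjusted p = 0.137). The list also took in the similar to dihydrofolate synthetase/folylpolyglutamate synthetase gene Os10g0503200, of folate metabolism (−1.45, SE 0.43). The call was lost without control replicate 3 (median −0.27, adjusted p = 0.111), without treated replicate 3 (−0.24, adjusted p = 0.115) and with specific probes only (−0.13, adjusted p = 0.337), and over all alternatives its adjusted p ran from 0.00315 to 0.977.

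The fixed list of histones and cell cycle had also taken in F-box proteins with a cyclin-like domain; its 303 genes had a median of 0.10, a mean of −0.01 and a limma camera adjusted p of 0.917. Its member with the smallest p was the F-box gene Os08g0293200, given above. Without F-box proteins, a narrowing made before any change between groups was computed, the 109 remaining genes had a median of −0.34 (limma camera adjusted p = 3.59e-06; adjusted p = 0.977 with an estimated correlation). Adjusted over this list alone 0 rose and 28 fell, among them the cyclin-A3-1 gene Os03g0607600 (−1.77, SE 0.34), the cyclin-dependent kinase B2-1 gene Os05g0483801 (−1.73, SE 0.33) and the histone H2A gene Os10g0418000 (−1.63, SE 0.32), of mitotic control and chromatin packing. Treated means were −0.72, −0.23 and −0.43 against control means of −0.26, 0.02 and 0.24, so treated replicate 2 lay above control replicate 1. The median was −0.15 with no filter on dim probes.

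**Figure D2:**
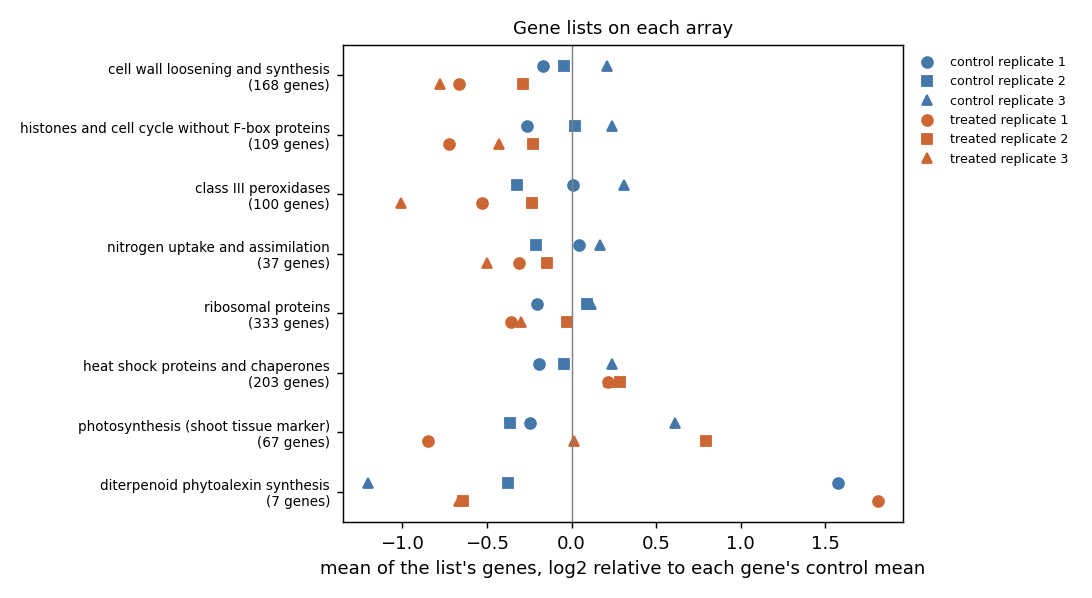
Mean of the genes of 8 lists on each array, in log2 units relative to each gene's control mean, with colours for group and symbols for replicate. In the cell wall list the treated arrays lie at −0.67, −0.29 and −0.78 and the controls at −0.17, −0.04 and 0.21, whereas photosynthesis and phytoalexin genes do not separate by group.

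The other 27 fixed lists were not called, with limma camera adjusted p of at least 0.209, and no member of 29 of the 31 lists passed over all genes. Defence genes lay on both sides of 0. Medians were 0.16 for 121 pathogenesis-related genes, 0.04 for 73 WRKY factors, 0.17 for 7 diterpenoid phytoalexin genes, −0.20 for 58 phenylpropanoid genes and 0.12 for 28 flavonoid genes. They were 0.12 for 48 antioxidant enzymes, 0.03 for 49 glutathione S-transferases, 0.08 for 55 genes of microbe perception and common symbiosis, −0.06 for 115 receptor-like kinases and 0.13 for 160 cytochromes P450. The signal level and GC correction turned phytoalexin genes to −0.04, glutathione S-transferases to −0.08 and WRKY factors to −0.0005, while the other lists here kept their sign. Phenylpropanoid genes were called lower without control replicate 2 (−0.33, limma camera adjusted p = 0.00788) and without treated replicate 2 (−0.14, adjusted p = 0.0261). The members with the smallest p included WRKY30, Os08g0499300 (log2 difference 1.43, SE 0.27), the stemar-13-ene synthase gene Os11g0474800 (1.28, SE 0.39), the cupredoxin gene Os01g0850700 (1.76, SE 0.33) and the dihydroflavonol-4-reductase gene Os03g0184550 (1.74, SE 0.47). Os12g0613250, described as similar to BTB/POZ superoxide dismutase, differed by −1.35 (SE 0.32) and the glutathione S-transferase gene Os10g0543800 by −1.06 (SE 0.23). Values of the thaumatin gene Os11g0703000, the nodulin-like gene Os02g0331400 and the BAK1-like receptor kinase gene Os01g0935800 were at least 4.30-fold, 4.82-fold and 4.95-fold lower, and that of the cytochrome P450 gene Os03g0741500 at least 2.88-fold higher.

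Hormone lists had medians of −0.03 for 38 ethylene genes, −0.14 for 36 jasmonate genes, −0.09 for 115 auxin genes, 0.10 for 38 cytokinin genes, −0.01 for 19 gibberellin genes and 0.08 for 91 abscisic acid and dehydration genes. Jasmonate genes were called lower without control replicate 2 (median −0.52, limma camera adjusted p = 0.0233). The ethylene-responsive factor 5 gene Os01g0657400 differed by −2.28 (SE 0.34), the lipoxygenase L-2 gene Os03g0738600 by −1.67 (SE 0.32) and the auxin-induced beta-glucosidase gene Os11g0673200 by 1.82 (SE 0.28). Differences were −1.91 (SE 0.38) for the response regulator gene Os01g0971800, −2.15 (SE 0.32) for the gibberellin-induced stem elongation gene Os02g0776900 and 1.06 (SE 0.24) for the protein phosphatase 2C gene Os06g0698300. Salicylate signalling had 4 measured genes and was not tested; its NPR1-like gene Os01g0194300, a regulator of salicylate responses, differed by 0.89 (SE 0.21).

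Nutrient and transport lists had medians of −0.13 for 39 phosphate genes, −0.35 for 25 iron and zinc genes, −0.09 for 56 organic acid genes, −0.07 for 68 sugar genes and −0.15 for 9 aquaporins. With quantile normalisation the aquaporin median was 0.004. The phosphate transporter gene Os02g0593500 differed by −2.44 (SE 0.43), with treated signal below background. The metal-nicotianamine transporter YSL2 gene Os04g0542800 differed by −0.95 (SE 0.34), the malate synthase gene Os04g0486950 by 1.15 (SE 0.22), the sugar transporter gene Os11g0643800 by −3.51 (SE 0.61) and the aquaporin NIP3-1 gene Os10g0513200 by −1.15 (SE 0.26). Medians were 0.07 for 198 MYB, NAC and bHLH factors, 0.19 for 203 heat shock proteins and chaperones and 0.11 for 11 fermentation genes. The heat shock list was called higher on the 4 scanner arrays (0.22, limma camera adjusted p = 0.0221) and without control replicate 3 (0.26, adjusted p = 0.0134). Among them the NAM-domain gene Os02g0214500 was at least 5.41-fold higher in value, the heat shock factor gene Os09g0455200 differed by −1.41 (SE 0.30) and the pyruvate decarboxylase gene Os01g0160100 by 1.06 (SE 0.26).

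The lists for other tissues that a root sample could hold were not called on the 6 arrays. The 67 photosynthesis genes, a marker of shoot tissue, had a median of −0.02 (limma camera adjusted p = 0.936) and means of −0.24, −0.37 and 0.61 on the control arrays and −0.85, 0.79 and 0.02 on the treated arrays. Within the slide that holds both groups, where 1 treated array informs the difference, the median of these genes was −0.64. That was a larger shift than in the cell wall (−0.41), cell cycle (−0.28) and ribosomal protein (−0.27) lists there. The chlorophyll a-b binding protein gene Os09g0346500 of the photosynthesis list differed by −1.52 (SE 0.42). The 37 seed storage genes had a median of 0.07 and a limma camera adjusted p of 0.751, with the lipid transfer protein and seed storage domain gene Os01g0914300 at −2.63 (SE 0.28). Median, mean and test direction differed in sign in 6 lists, none of them called: glutathione S-transferases, cytokinin, microbe perception, histones and cell cycle, photosynthesis and seed storage. The narrowed lists of pathogenesis-related proteins without ERF-domain factors, ERF-domain factors and seed storage without lipid transfer proteins had medians of 0.17, −0.08 and −0.03 and were not called on the 6 arrays.

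The second comparison used the scanner signal of the 2 control and 2 treated arrays that had it, 3 of them on 1 slide. These arrays are among the 6 of the first comparison, so their values are no independent check of it. Os11g0539200 was at −3.45 and Os11g0658700 at 2.99. In limma 0 genes passed, the lowest adjusted p was 0.223, and 3327 genes had an unadjusted p under 0.05. On simulated data 4 arrays recovered 0% of genes changed by up to 4 log2 units. The count of 0 therefore cannot show whether single genes changed.

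With slide as a block, only control replicates 1 and 2 and treated replicate 1 informed the difference. Differences were then −3.40 for Os11g0539200 and 2.82 for Os11g0658700. No value is given for Os01g0909150, Os03g0829600, Os04g0532400 and Os10g0566800, which lay below background in a group. Limma adjusted p of the 6 genes ran from 0.0807 to 0.123. Within that slide the cell wall list had a median of −0.41, the cell cycle list without F-box proteins −0.28 and ribosomal proteins −0.27. Peroxidases had −0.01, nitrogen genes −0.16, photosynthesis genes −0.64 and heat shock genes 0.22. The narrowed list of pathogenesis-related proteins without ERF-domain factors had 0.41. No p is given for these medians, because 1 treated array informs them and a list p there measures spread over genes, not over samples. The slides of control replicate 3 and treated replicate 2 were not given in the files used here.

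The slide block called 42 genes in limma, all lower, and none of the 6 was among them. Their median against the control mean was −6.66 on treated replicate 1 but 0.04 and −0.13 on treated replicates 2 and 3. Of their 43 spots, 41 lay in rows 66 to 130 and columns 27 to 39 of the array, which has 532 rows and 85 columns. In that patch 24.1% of 555 tested probes read at least 2 log2 units below the median of the other scanner arrays on treated replicate 1, against 0.18% on control replicate 1, 0.90% on control replicate 2 and 1.44% on treated replicate 3. Without the probes of the patch the slide block called 0 genes in limma, with 2901 at an unadjusted p under 0.05, and the 6-array count was 18, 2 higher and 16 lower, including all 6 genes.

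**Figure D3:**
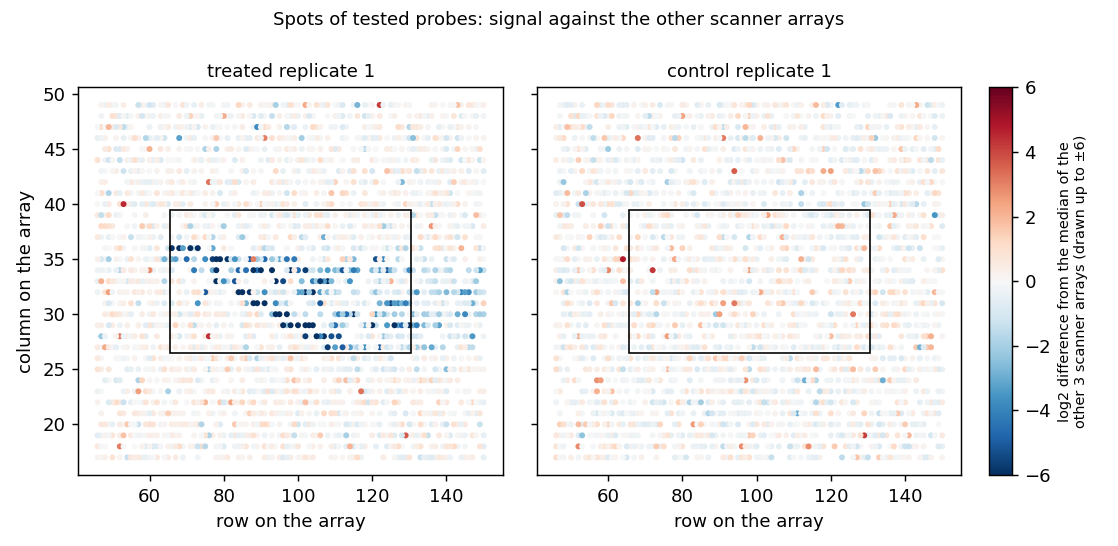
Log2 signal of each spot of a tested probe relative to the median of the other 3 scanner arrays, by row and column, on treated replicate 1 and, for comparison, control replicate 1; the box marks rows 66 to 130 and columns 27 to 39. Low spots form a streak on treated replicate 1 that also runs past the box toward higher rows, and control replicate 1 has no such streak.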

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

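The signal level and GC correction, specific probes only and the failed patch left out were chosen after seeing the data. The count of 6 genes on 6 arrays moved widely, and the cause was not tested unless stated. It was 119 with quantile normalisation, 21 with median centring, 63 with array weights, 201 with the signal level and GC correction, 249 with that correction and treated replicate 1 left out, 46 with specific probes only, 18 with the failed patch left out and 3162 for at least 1 on the log2 scale with no test. All 6 genes were among these calls for quantile normalisation, centring, weights, the correction with 6 arrays and the patch left out. The genes added with the patch left out lay close to the threshold in both fits. Their limma adjusted p was 0.0512 in the main fit and 0.0466 to 0.0495 without the patch. With specific probes only the calls held 5 of the 6, and Os11g0539200 had no probe to test. The count was 0 in limma with no filter on dim probes, probes above background on all 4 scanner arrays, the 4 scanner arrays, and the variance trend. All 6 genes were well above background on both scanner arrays of 1 group only. They were therefore left out, not tested, with probes above background on all 4 scanner arrays. With each array left out in turn the count ran from 0 to 725, and was 0 except without treated replicate 1. The 4 scanner arrays had 3327 genes at an unadjusted p under 0.05, and the other 9 alternatives with 0 genes, the replicate block included, 3109 to 4945.

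With a replicate block 0 genes passed in limma, with 3682 at an unadjusted p under 0.05, and the list count stayed at 4. Deviations of same-numbered samples correlated across genes at 0.30, −0.28 and −0.30, so the numbers do not pair the samples, and only number 1 correlated best with its own number. Control replicate 3 correlated at 0.51 with treated replicate 2, and control replicate 2 at 0.43 with treated replicate 3. Control and treated arrays thus varied together under other numbers, and why was not tested. For the 4 scanner arrays, no paired analysis was possible because the groups share fewer than 2 numbers. There the count of 0 became 42 with slide as a block, ran from 0 to 42 with each array left out, and was 0 otherwise, with 2029 to 3868 genes at an unadjusted p under 0.05. Leaving out treated replicate 3 gives the same fit as the block, with a lone treated array assumed to vary like the controls.

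The 4 shifted lists became 0 with an estimated correlation, 0 with directional fry and 20 with mixed fry, and 3 to 6 with each array left out. They were 5 on the 4 scanner arrays and 4 without control replicate 3, and in both of these 1 list, heat shock proteins and chaperones, was called higher. With the estimated correlation no call was kept. The medians could not move there, since the correlation enters only the p. They were −0.48 for cell wall, −0.39 for peroxidases, −0.38 for nitrogen, −0.23 for ribosomal proteins and −0.34 for the cell cycle without F-box proteins. With no filter on dim probes the medians were −0.10 for cell wall, −0.15 for the cell cycle without F-box proteins and −0.17 for peroxidases, all still called. Nitrogen also lost its call with specific probes only (−0.13), without control replicate 3 (−0.27) and without treated replicate 3 (−0.24), with medians from −0.48 to −0.24 over the arrays left out; those of peroxidases ran from −0.65 to −0.14. The 50 named genes kept their direction in all 823 values. Their groups do not overlap on the 6 arrays, so leaving out arrays could not reverse them. The 6 past the threshold kept the call in 41 values and lost it in 54, and the other named genes gained one in 113. Dim signal limits the comparison, since 4 of the 6 genes were below background in a group on the scanner arrays.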

Other observations

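The families described here were chosen after the list results were seen, and the test of spot positions was chosen after the genes' values were seen. Within the cell wall list, 32 of 39 expansins, wall-loosening proteins, were lower in value (median −1.18), and 8 fell adjusted over the list alone. Expansin means were −0.34, −0.27 and 0.60 on the control arrays and −0.89, −0.33 and −1.61 on the treated arrays, so treated replicate 2 lay within the controls' range. Of 26 xyloglucan enzymes 23 were lower (median −0.65), of 22 cellulose synthases and related genes 17 (−0.58) and of 20 extensins 17 (−0.53), with 8, 8 and 6 that fell adjusted over the list alone. These medians were negative under quantile normalisation, centring and the signal level and GC correction too. Of 37 pectinesterases and their inhibitors 18 were lower in value (median 0.02, and −0.06 with quantile normalisation), and adjusted over the list alone 1 rose and 7 fell. Of 18 polygalacturonases 10 were lower (median −0.04), and 1 rose and 6 fell.

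Among cell cycle genes, 38 of 49 core histones were lower in value (median −0.37), 12 of which fell adjusted over the list alone, though the mean of treated replicate 2 (−0.17) lay above that of control replicate 1 (−0.36). So were 6 of 7 A- and B-type cyclins (median −1.52), of which 4 fell. The 4 linker histones had a median of 0.21. Ribosomal proteins of the small and large subunit were lower in 87 of 121 and 137 of 191 genes. Some lists varied within groups more than between them. Phytoalexin genes had means of 1.58, −0.38 and −1.20 on the control arrays and 1.81, −0.64 and −0.67 on the treated arrays. Jasmonate genes had 0.60, −0.46 and −0.14 against 0.23, −0.30 and −0.67. Both lists were highest on replicate 1 of each group.

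The first pattern is the 42 genes that the slide block called. A candidate explanation is failed spots in a patch of the array of treated replicate 1. The median distance from each spot to the nearest other was 2, against a median of 16.03 in random draws, at percentile 0 of 10000 draws, which is what this explanation predicts. Their medians were 0.04 and −0.13 on treated replicates 2 and 3, and 2 of the 42 had an unadjusted p under 0.05 over the 6 arrays, so a change with treatment in single genes stays open. None of the 6 genes, 1 named gene (Os01g0758000) and 6 of the 725 genes called without treated replicate 1 lay in the patch.

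The second pattern is the rise from 6 to 725 genes without treated replicate 1. A slide effect or a wrong label, under which that array would lack the change, was argued against for the lower genes only. Of genes chosen on replicates 2 and 3, 83.3% had the same sign in treated minus control replicate 1. That share passed the limit set beforehand, but so did the 67.7% of all genes. It was 97.6% for the 291 lower genes chosen. For the 434 higher genes chosen it was 73.7%, near that of all genes, so the test could not decide for them. Of the 725 genes called without treated replicate 1, a different set, 545 were higher. Because 0 genes passed on those 4 arrays in limma, the 725 with the smallest p were used there, not called genes as first set out. Differences between arrays that follow signal level and GC stay open: after that correction 249 genes passed, holding 139 of the 545 higher and 94 of the 180 lower genes and 16 others, the median log2 of the higher genes going from 1.92 (median SE 0.27) to 1.62 (0.27) and of the lower from −2.00 (0.30) to −2.22 (0.29), so differences shrank among the higher genes, while why lower calls ended was not tested. The higher genes were dim (median control level −5.41, against −1.14 for all genes) and had a median of 0.32 on treated replicate 1, with 57.4% above every control there, and a weaker response in them stays open and was not tested; the lower genes had −1.96 on that array, against −2.00 without it, with 98.9% below every control.

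The third pattern is the 5 lists that were lower: cell wall, peroxidases, cell cycle without F-box proteins, ribosomal proteins and nitrogen. After the signal level and GC correction their medians, in that order, were −0.53, −0.50, −0.385, −0.31 and −0.33, and the count of fixed lists called stayed at 4. These values argue against differences between arrays that follow signal level and GC as the whole cause. Medians of 5 of 5 lists also lay below the 2.5th percentile of matched random lists. That limit could not decide, since the lists were picked as lower in these same arrays and random genes lack their correlation. Lists that were not called met that limit too: phenylpropanoid (percentile 0.06), iron and zinc (0.07), auxin (0.61), jasmonate (1.64) and organic acid genes (2.21). A slide effect cannot be told apart for all of them: within the slide that holds both groups 3 of 5 lists lay below that percentile, as did photosynthesis genes, a shoot marker (−0.64), and auxin genes (−0.19), and only 1 treated array informs this test. Treatment with the bacterium and chance stay among the open explanations.

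The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 split, the real one, gave 6 genes and the highest of the others gave 0. For lists, 8 of 10 splits, the real one included, gave at least the real 4, so that count does not set the real grouping apart. The highest other gave 15. That split set control replicates 1 and 3 and treated replicate 1 against the rest, with 0 genes in limma and 1286 at an unadjusted p under 0.05. The list counts rest on the preset correlation of 0.01, and the estimated correlations of the 5 lower lists ran from 0.0265 to 0.326. The split that set control replicates 1 and 2 and treated replicate 1, known to share a slide, against the rest also gave 4 lists, and 0 genes in limma with 2016 at an unadjusted p under 0.05; the medians within that slide are given with the slide block.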
